A study of Mus musculus with 7 samples.

How the data were processed

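RNA was measured on 7 microarrays, 1 per sample, from LSK cells of mouse bone marrow. LSK cells carry no markers of mature lineages and carry Sca-1 and c-Kit, the gate that holds haematopoietic stem cells and early progenitors. Per the labels, 4 samples came from mice in which Lkb1 was deleted by a tamoxifen-activated Cre recombinase expressed from the Rosa26 locus (Lkb1 KO, numbers 4 to 7), and 3 from tamoxifen-treated mice with the floxed gene and without Cre (Lkb1 WT, numbers 5 to 7). Cre was therefore present in the KO mice alone. Cells were sorted 1 day after 5 days of tamoxifen, 15000 to 20000 per sample, and about 10 ng of total RNA was amplified and labelled with biotin, per the labels' protocols. The labels do not say in words that each sample came from a separate animal, so p-values measure the spread between these samples, which may be technical.

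The deposited table holds 1 signal intensity per probe set and array on a linear scale. The submitters' processing notes name MAS5 as the tool, and its settings, scaling target and version are not given in the sources used here. The table holds 22690 probe sets, 64 of them controls, and no detection calls are used here. Its probe sets were named through the platform annotation table, in which 20393 had 1 gene symbol, 691 had several and 1555 had none. Of the probe sets with 1 symbol, 20364 matched the gene table of the mouse assembly GRCm38.p6, which was used for names and for which genes neighbour each other. No gene was named from a probe set with several symbols. The labels name the 430 2.0 array, while the number of probe sets is that of a smaller design, and the cause is not known here.

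Intensities were analysed as log2(signal + 16). The design fixed before the data were examined took the deposited intensities as already scaled between arrays. They were not, since the trimmed means of the arrays, without 2% at each end, ranged from 230.3 to 428. Quantile normalization across the 7 arrays over non-control probe sets, an alternative fixed beforehand, was therefore used for the main values, a choice made before any model was fitted. The scaling as deposited is given as an alternative. Fold changes are on the log2(signal + 16) scale, which understates the change of dim genes. A probe set entered the tests when its mean lay above the 40th percentile of non-control probe sets, and each gene was represented by its brightest probe set with 1 symbol. This left 8077 genes. As a measure of background, 27 control probe sets for transcripts that were not added gave a 95th percentile of 13.64 signal units over 189 readings.

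KO and WT were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, an intercept and genotype, 5 residual degrees of freedom), with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. Gene lists were fixed before the data were examined. The 36 lists covered the LKB1 and AMPK-related kinases, signalling and metabolic pathways, the cell cycle, stress responses, blood lineages, other cell types of bone marrow, sex-linked genes and genes near the Rosa26 locus. They were tested with limma's camera at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 35 lists with at least 5 genes tested. Camera with a correlation estimated from the data, and fry, which asks whether a list's genes move on balance one way, were alternatives. Another 8 lists were added after the main results were seen and are adjusted among themselves. Members of a list were counted as past the threshold over all genes, and again with p adjusted over the list alone. Values of single measures were compared by two-sided exact permutation tests over the 35 splits of the samples into 4 and 3, where the smallest possible p is 0.0286.

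Genes named in the text follow a rule fixed before the data were examined. It takes Stk11, the 10 largest rises and 10 largest falls among genes past the threshold whose groups did not overlap, up to 4 members of lowest p from every list, and a fixed set of genes. Of that set, Ppara, Sik1 and Hba-a1 lay below the filter, and Ddx3y had no probe set of its own. A further gene of the set is not reported here. Genes outside the rule are said to be chosen after their values were seen. Alternatives covered the pseudocount (1, 64, or a floor of 32), the scaling (as deposited, median centring, and cyclic loess, which was added later), the filter (none or the 60th percentile), the use of several probe sets per gene, the prior variance, array weights, the replicate number as a block, the 3' to 5' ratio of Actb as a covariate, and leaving out each sample in turn. The sex of the animals was not used as a covariate, since the sex-linked genes showed the same pattern in all 7 arrays. On simulated data with the real samples' means and spread, 8081 genes entered the test, among them 89 changed by 1 log2 unit and 94 changed by 0.5. Of these limma recovered 67 (75.3%) and 23 (24.5%), with 6 false calls among 96. Probe sets were simulated independently of each other, so errors shared between genes, which can change the share of false calls, were not covered. The number of arrays limits the precision.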

Results

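The series compared gene expression in samples of LSK cells from Lkb1 KO mice (4 samples) and Lkb1 WT mice (3 samples) 1 day after tamoxifen, which addresses the early response of stem and progenitor cells to loss of the kinase Lkb1 (gene Stk11). The arrays differed in brightness before normalization, with a trimmed mean signal of 388.5 ± 30.6 (SD, n = 4) in KO and 297.4 ± 59.3 (SD, n = 3) in WT (exact permutation p = 0.0286, the smallest possible). Each KO array was brighter than each WT array, and the dimmest was Lkb1 WT 7 at 230.3. The hybridization controls, added in fixed amounts, differed by -0.0945 log2 units (KO minus WT, exact permutation p = 0.171). The 3' to 5' signal ratio of the Actb controls, a sign of RNA length after amplification, was 11.41 to 12.29 in KO and 12.6 to 13.11 in WT (exact permutation p = 0.0571). For the Gapdh controls the ratio did not separate the groups (exact permutation p = 0.6).

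**Figure D1:**
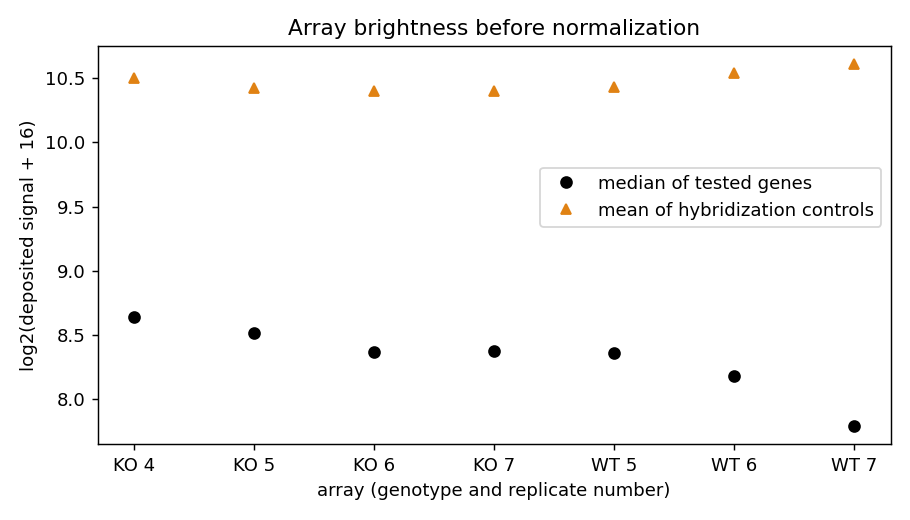
Brightness of each array before normalization, as log2(deposited signal + 16), for the median of tested genes (circles) and the mean of the hybridization controls (triangles), 1 point per array. The gene medians of the 4 KO arrays lie between 8.37 and 8.64 and those of the 3 WT arrays between 7.79 and 8.36, while the controls lie between 10.4 and 10.61 on all arrays.

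The lists of mature granulocyte and monocyte genes and of stem cell genes were lower in KO, and lists of genes for DNA replication, ribosome biogenesis and mitochondrial translation were higher, each as a set in camera's test. None of these 5 calls held with an estimated correlation. Adjusted p was then 0.186 for granulocyte and monocyte, 0.134 for stem cell, 0.099 for S phase, 0.176 for ribosome biogenesis and 0.134 for mitochondrial ribosome genes. The stem cell median was 0.00 in the scaling as deposited. Of 8077 genes tested, 200 rose and 239 fell in KO (limma, Benjamini-Hochberg adjusted p under the threshold of 0.05), and 2046 had an unadjusted p under 0.05. A change of 2-fold or more was reached by 14 of the genes that rose and 35 of those that fell. KO and WT values did not overlap for any of the 439 genes, and did not overlap for 24.1% of all tested genes, where chance gives 5.71%. The first principal component held 36.5% of the variance and separated the genotypes. All directions are relative to the median gene, since the deposited signals of tested genes were shifted upward in KO by a median of 0.34 log2 units. Without normalization 1372 genes were higher and 43 lower, so that 97.0% of calls were higher, against 45.6% after it.

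The number of calls depended on each of the samples. It was 51 higher and 90 lower without Lkb1 KO 4, 45 and 91 without KO 5, 76 and 119 without KO 6, and 8 and 37 without KO 7. Without Lkb1 WT 5 it was 43 and 55, without WT 6 it was 29 and 63, and without WT 7 it was 26 and 35. Of the 439 genes, 31 passed in each of these 7 fits, 174 passed in none, and no sign changed. Among the 31 were Greb1, Lcn2, Ltf, Fpr2, Chil3, Ngp, Camp, S100a9, Fn1, Hlf, Pdzk1ip1, Trib3, Ccl3 and Txnip, which fell, and Hspd1, Ly86, Nrp1 and Rps27l, which rose. With the Actb 3' to 5' ratio as a covariate, which separated the groups, no gene passed in limma and 713 had an unadjusted p under 0.05.

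Stk11 itself was measured by 2 probe sets, and whether they lie in the deleted part of the gene is not known here, so they do not check the labels. The brighter probe set gave 6.82 ± 0.33 (SD, n = 4) in KO and 7.38 ± 0.24 (SD, n = 3) in WT on the log2 scale, a difference of -0.56 with overlapping groups (limma adjusted p = 0.117, exact permutation p = 0.0857). Its deposited signals were 162.5, 123.4, 91.2 and 74.1 in KO 4 to 7 and 187.3, 115.2 and 99.3 in WT 5 to 7. The dimmer probe set exceeded the background level on 3 of 4 KO arrays and on 1 of 3 WT arrays. Its mean deposited signal in WT, 9.3, lay below that level, so no difference is given for it. Its values overlapped between the groups (exact permutation p = 0.143), and nothing is concluded from it. None of the 12 tested genes of the list of LKB1 complex members and AMPK-related kinases passed the threshold, with 1 lower when adjusted over the list alone (camera adjusted p = 0.327). Its member of lowest p was the kinase gene Snrk, at -0.58 (limma adjusted p = 0.0586).

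Values in parentheses after gene names below are log2 fold changes, KO minus WT, with the standard error from limma. The largest fall was in Greb1, a gene known for its induction by estrogen (-2.99 ± 0.28, adjusted p = 0.00644), from 9.52 ± 0.21 (SD, n = 3) in WT to 6.53 ± 0.56 (SD, n = 4) in KO. Most other large falls were in genes of neutrophil granules and of mature myeloid cells. They were Lcn2 (-2.26 ± 0.27), lactoferrin gene Ltf (-2.24 ± 0.25), formyl peptide receptor gene Fpr2 (-2.21 ± 0.29), Ear3 (-2.06 ± 0.33), Chil3 (-1.96 ± 0.23), neutrophilic granule protein gene Ngp (-1.90 ± 0.16), cathelicidin gene Camp (-1.83 ± 0.16) and S100a9 (-1.75 ± 0.22). Fibronectin gene Fn1 fell as well (-1.75 ± 0.21). In the list of mature granulocyte and monocyte genes, 12 of 15 tested members fell and 1 rose, with a median of -1.51, and 12 fell and 2 rose when adjusted over the list alone. The list fell as a set (camera adjusted p = 2.15e-08; adjusted p = 0.186 with an estimated correlation). The member that rose was F13a1, the coagulation factor XIII A subunit of monocytes and platelets.

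The largest rise was in Cdkn1a, the cyclin-dependent kinase inhibitor p21 (1.66 ± 0.24, adjusted p = 0.0179), from 7.18 ± 0.40 (SD, n = 3) to 8.84 ± 0.37 (SD, n = 4). It was followed by F13a1 (1.42 ± 0.26), the inhibitory receptor gene Pdcd1 (1.37 ± 0.30), neuropilin gene Nrp1 (1.34 ± 0.17), Rnf19b (1.21 ± 0.28), Ly86 (1.17 ± 0.12), Spsb4 (1.08 ± 0.18), Anxa3 (1.07 ± 0.16) and the mitochondrial chaperonin gene Hspd1 (1.05 ± 0.13). The proline-catabolic gene Aldh4a1 also passed as higher, but its mean deposited signal in WT, 13.4, lay below the background level of 13.64, so no fold is given for it. Pdcd1 and Rnf19b were little above that level in WT, with mean signals of 14.7 and 15.0, so their folds are uncertain. The background level was exceeded on 2 of 3 WT arrays for Pdcd1 and on 1 for Rnf19b and Aldh4a1, and on all 4 KO arrays for each. Without each sample in turn, Cdkn1a passed in 5 of 7 fits, Anxa3 in 4, Spsb4 in 2 and F13a1, Pdcd1, Rnf19b and Aldh4a1 in 1. A second probe set of Cdkn1a, near background, exceeded that level on 3 of 4 KO arrays and on no WT array.

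**Figure D2:**
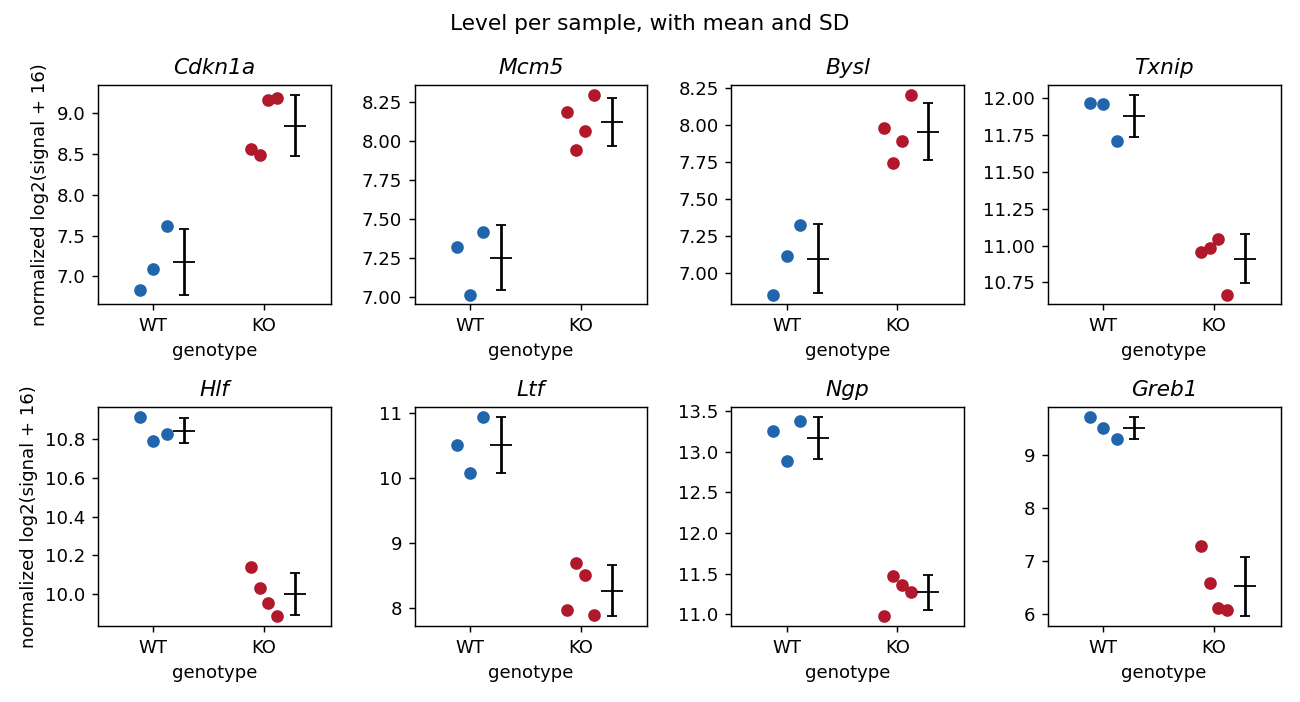
Normalized log2(signal + 16) of 8 genes in each sample, with WT in blue and KO in red, and the mean and SD of each group as a bar beside the points (3 WT and 4 KO samples). Cdkn1a, Mcm5 and Bysl were higher, and Txnip, Hlf, Ltf, Ngp and Greb1 lower, in each KO sample than in any WT sample. Each panel has its own vertical range, which does not start at 0.

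Genes of DNA replication were higher as a set. In the S phase list, 15 of 37 tested members rose and none fell, 28 rose when adjusted over the list alone, and the median was 0.41 (camera adjusted p = 4.7e-15; adjusted p = 0.099 with an estimated correlation). The helicase genes Mcm5 (0.87 ± 0.13) and Mcm2 (0.52 ± 0.09), the histone chaperone gene Nasp (0.61 ± 0.09) and the exonuclease gene Exo1 (0.66 ± 0.11) were those of lowest p. The count of 15 was 0 without Lkb1 KO 7 and at most 5, without KO 6. Of 48 genes of the G2 and M phase, 4 rose and none fell, 6 when adjusted over the list alone, with a median of 0.22 (camera adjusted p = 5.02e-07; adjusted p = 0.24 with an estimated correlation). They were Bub1 (0.54 ± 0.10), Anp32e (0.56 ± 0.10), Birc5 (0.69 ± 0.15) and Cdk1 (0.38 ± 0.09). The count of 4 was 0 or 1 in the 7 fits without 1 sample. Bub1, Birc5 and Cdk1 passed in none of them and Anp32e in 1. Mki67, a proliferation marker, was at 0.20 (adjusted p = 0.345) and cyclin gene Ccnd1 at 0.23 (adjusted p = 0.349).

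Among cell cycle inhibitors and quiescence genes, Cdkn1a rose while Txnip (-0.97 ± 0.12) and cyclin gene Ccng2 (-0.63 ± 0.10) fell, and the other 21 of 24 did not pass. Adjusted over the list alone, 2 rose and 9 fell. The list was lower as a set, with a median of -0.27 (camera adjusted p = 0.0417; adjusted p = 0.348 with an estimated correlation), and its median was 0.04 in the scaling as deposited. It did not pass without Lkb1 KO 5 (adjusted p = 0.0548) or KO 7 (adjusted p = 0.116), with the Actb 3' to 5' ratio as a covariate (adjusted p = 0.515) or with the replicate number as a block (adjusted p = 0.0633). Cdkn1b was at -0.59 (adjusted p = 0.0584) and Cdkn1c at -0.19 (adjusted p = 0.492). Of 22 p53 target genes, Rps27l (0.86 ± 0.09), Zmat3 (0.74 ± 0.15) and Cdkn1a rose and none fell, also when adjusted over the list alone, and the list did not pass as a set (median -0.01, camera adjusted p = 0.458). Without Lkb1 KO 7, 1 of these p53 targets rose, and among the inhibitors 1 fell and none rose. Trp53inp1 was at -0.33 (adjusted p = 0.422). None of 20 apoptosis regulators passed, 1 higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.77), with Birc2 at -0.43 (adjusted p = 0.0525), Bcl2 at -0.08 (adjusted p = 0.853) and Mcl1 at -0.15 (adjusted p = 0.37; 0.13 in the dimmest of its probe sets).

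Genes for making ribosomes and for mitochondrial translation and respiration were also higher as sets. In the ribosome biogenesis list 6 of 35 rose and none fell, 17 when adjusted over the list alone, with a median of 0.31 (camera adjusted p = 2.05e-09; adjusted p = 0.176 with an estimated correlation). Bysl (0.86 ± 0.15), Nolc1 (0.73 ± 0.16), Nhp2 (0.60 ± 0.11) and Nop58 (0.53 ± 0.11), which act in processing of ribosomal RNA, led the list. Of 72 mitochondrial ribosome genes 6 rose and none fell, 16 when adjusted over the list alone, with a median of 0.20 (camera adjusted p = 3.27e-08; adjusted p = 0.134 with an estimated correlation), among them Mrps22 (0.49 ± 0.09), Mrpl18 (0.53 ± 0.10), Mrps14 (0.47 ± 0.09) and Mrpl20 (0.60 ± 0.13). In oxidative phosphorylation 3 of 71 rose and none fell, also when adjusted over the list alone, with a median of 0.17 (camera adjusted p = 8.54e-08; adjusted p = 0.176 with an estimated correlation). They were Ndufc1 of complex I (0.56 ± 0.09), Uqcrq of complex III (0.65 ± 0.11) and Atp5k of the ATP synthase (0.81 ± 0.16). Of 24 TCA cycle genes Dld (0.70 ± 0.10) and Dlst (0.66 ± 0.15) rose and none fell, 5 when adjusted over the list alone, with a median of 0.16 (camera adjusted p = 0.000675; adjusted p = 0.134 with an estimated correlation). Without 1 sample the member counts ranged from 0 to 3 for ribosome biogenesis and from 0 to 2 for the mitochondrial ribosome. They ranged from 0 to 3 for oxidative phosphorylation and from 0 to 2 for the TCA cycle.

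Several metabolic and signalling lists did not pass as sets. In glycolysis, lactate dehydrogenase gene Ldha (0.65 ± 0.11) and lactate transporter gene Slc16a1 (0.58 ± 0.13) rose among 17, 4 when adjusted over the list alone (median 0.16, camera adjusted p = 0.105). Of 28 genes of PGC-1, PPAR and fatty acid oxidation, the acyl-CoA dehydrogenase gene Acadl rose (0.37 ± 0.09) and none passed when adjusted over the list alone (median -0.06, camera adjusted p = 0.663). The coactivator genes Ppargc1a and Ppargc1b were at -0.89 (adjusted p = 0.189) and -0.04 (adjusted p = 0.929). The other, dimmer probe sets of Ppargc1a ran from -0.44 to 0.10. In the mTORC1 list the folliculin gene Flcn fell (-0.53 ± 0.08) among 21, 2 when adjusted over the list alone (median -0.08, camera adjusted p = 0.411), and Ddit4 was at -0.18 (adjusted p = 0.761). Of 40 autophagy and lysosome genes 4 fell and none rose, 4 and 1 when adjusted over the list alone (median -0.02, camera adjusted p = 0.845). They were the initiating kinase gene Ulk1 (-0.61 ± 0.09), Wipi1 (-0.68 ± 0.14), Map1lc3b (-0.38 ± 0.09) and Gabarapl1 (-0.39 ± 0.09, and 0.01 in the scaling as deposited). The count of 4 ranged from 0 to 1 in the 7 fits without 1 sample. Ulk1 passed in 4 of them, and Wipi1, Map1lc3b and Gabarapl1 in none. The count of 2 in glycolysis ranged from 0 to 1, with Ldha past the threshold in 3 of the 7 fits and Slc16a1 in none. In sterol and fatty acid synthesis the squalene epoxidase gene Sqle rose (0.73 ± 0.16) among 28, also when adjusted over the list alone (median -0.05, camera adjusted p = 0.77). Without each sample in turn, Flcn passed in 3 of 7 fits, Sqle in 1 and Acadl in none. None of 40 cytosolic ribosomal protein genes passed, nor did any when adjusted over the list alone (median -0.01, camera adjusted p = 0.845), with Rps10 at -0.37 (adjusted p = 0.136) in its brightest probe set. Of its other probe sets, 3 were lower by more, at -0.62, -0.60 and -0.55 (exact permutation p = 0.0286 for each, the smallest possible). Another was at -1.001 (exact permutation p = 0.2) and the dimmest at 0.47 (exact permutation p = 0.114). The ribosomal protein list passed downward with median centring (median -0.24, camera adjusted p = 0.00023). Of 20 antioxidant genes none passed on either count (median 0.07, camera adjusted p = 0.317), with Txn1 at 0.33 (adjusted p = 0.059; -0.42 in a dimmer probe set). In the lists of PGC-1, sterol, p53 and ribosomal protein genes the median lay below 0 while camera's direction was upward. That direction is relative to the other tested genes and not to 0.

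Stem cell genes were lower as a set. In the haematopoietic stem cell list 4 of 31 fell and none rose, 13 when adjusted over the list alone, with a median of -0.40 (camera adjusted p = 2e-07; adjusted p = 0.134 with an estimated correlation), and the median was 0.00 in the scaling as deposited. The transcription factor genes Hlf (-0.84 ± 0.10) and Gfi1b (-0.91 ± 0.19), Pdzk1ip1 (-1.02 ± 0.13) and the receptor gene Kit (-0.43 ± 0.10, and 0.01 in the scaling as deposited) were those that fell. The count was 2 or 3 without 1 sample. Hlf and Pdzk1ip1 passed in all 7 of these fits, Gfi1b in 1 and Kit in none. Procr was at -0.36 (adjusted p = 0.0566). In the myeloid progenitor list Nkg7 (0.58 ± 0.10), Ms4a3 (0.80 ± 0.15) and cathepsin G gene Ctsg (0.57 ± 0.12) rose and lysozyme gene Lyz2 fell (-0.81 ± 0.18) among 18, 9 and 1 when adjusted over the list alone, with a median of 0.23 (camera adjusted p = 0.000602; adjusted p = 0.275 with an estimated correlation). Without 1 sample, the number that rose ranged from 0 to 2 and the number that fell from 0 to 1. Nkg7 and Ms4a3 each passed in 2 of the 7 fits, and Ctsg and Lyz2 each in 1. Mpo was at 0.16 (adjusted p = 0.289). Of 14 lymphoid-primed progenitor genes Cd48 rose (0.47 ± 0.10), 2 when adjusted over the list alone (median -0.19, camera adjusted p = 0.464), with Cd48 past the threshold in none of the 7 fits without 1 sample. Flt3 was at -0.28 (adjusted p = 0.134).

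Markers of other lineages moved in both directions. Of 14 erythroid genes the membrane protein gene Ermap fell (-1.21 ± 0.20) and the globin gene Hba-a2 rose (0.43 ± 0.09), 11 fell and 1 rose when adjusted over the list alone, and the median was -0.48 (camera adjusted p = 8.9e-05; adjusted p = 0.134 with an estimated correlation). The carbonic anhydrase gene Car1 was at -1.05 (adjusted p = 0.0595). Of 12 megakaryocyte and platelet genes Plek fell (-0.78 ± 0.17, and 0.09 in the dimmest of its 3 probe sets), 2 when adjusted over the list alone, with a median of -0.29, or 0.09 in the scaling as deposited (camera adjusted p = 0.0188; adjusted p = 0.165 with an estimated correlation). Of 7 mast cell and basophil genes the high-affinity IgE receptor gene Ms4a2 (0.63 ± 0.12) and carboxypeptidase gene Cpa3 (0.58 ± 0.12) rose, 3 when adjusted over the list alone, with a median of 0.46 (camera adjusted p = 0.00694; adjusted p = 0.176 with an estimated correlation). Of 8 B cell and plasma cell genes Blk (-0.72 ± 0.10) and Cd22 (-0.64 ± 0.13) fell, 5 when adjusted over the list alone, with a median of -0.49 (camera adjusted p = 0.00245; adjusted p = 0.134 with an estimated correlation). Without 1 sample, the count of 2 was 0 in each case for mast cell and basophil genes. It ranged from 0 to 2 for B cell and plasma cell genes, where Blk passed in 4 of the 7 fits and Cd22 in 1. Hba-a2 and Thy1 passed in none of these 7 fits, Ermap in 4, Slc40a1 in 2, and Plek and Col1a2 in 1. With the Actb 3' to 5' ratio as a covariate the calls of the B cell list (adjusted p = 0.0561) and the megakaryocyte list (adjusted p = 0.1) were lost. With the filter at the 60th percentile those of the B cell list (adjusted p = 0.449) and the mast cell list (adjusted p = 0.0937) were lost. Thy1 rose (0.47 ± 0.10) among 6 T and NK cell genes, also when adjusted over the list alone (median -0.29, camera adjusted p = 0.554). The iron exporter gene Slc40a1 fell (-0.82 ± 0.14) among 14 macrophage and dendritic cell genes, also when adjusted over the list alone (median -0.06, camera adjusted p = 0.554). Collagen gene Col1a2 fell (-0.94 ± 0.21) among 7 stromal and endothelial genes, 1 lower and 1 higher when adjusted over the list alone (median -0.30, camera adjusted p = 0.458).

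**Figure D3:**
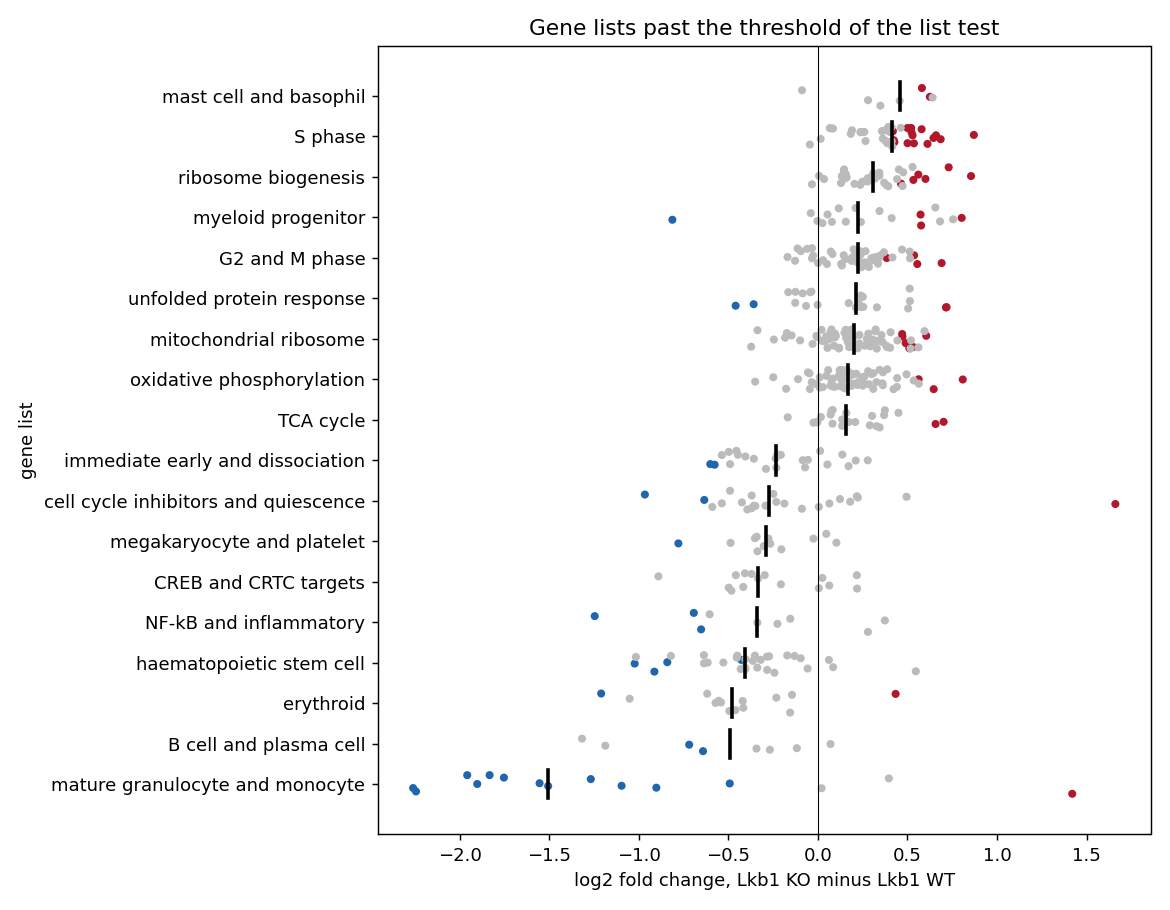
Log2 fold changes (KO minus WT) of the tested members of the 18 lists that passed camera's test, 1 point per gene, red for genes that rose, blue for genes that fell and grey for the others, with the list's median as a black bar. Medians run from -1.51 in mature granulocyte and monocyte genes to 0.46 in mast cell and basophil genes. In the scaling as deposited the medians of the lists of stem cell, megakaryocyte, immediate early, CREB and cell cycle inhibitor genes lie at or above 0.

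The lists of NF-kB, immediate early and CREB genes were lower as sets and that of the unfolded protein response was higher. None of these 4 calls held with an estimated correlation. The chemokine genes Ccl3 (-1.25 ± 0.12) and Ccl4 (-0.69 ± 0.10) and Tnfaip2 (-0.65 ± 0.10) fell among 9 NF-kB and inflammatory genes, 5 when adjusted over the list alone, with a median of -0.34 (camera adjusted p = 0.00447; adjusted p = 0.143 with an estimated correlation). Of 23 immediate early genes Nfkbiz (-0.58 ± 0.11) and Dusp2 (-0.60 ± 0.13) fell, 3 when adjusted over the list alone, with a median of -0.23, or 0.03 in the scaling as deposited (camera adjusted p = 0.0188; adjusted p = 0.44 with an estimated correlation). That list did not pass without Lkb1 KO 5 (adjusted p = 0.157) or WT 7 (adjusted p = 0.098). None of 15 CREB and CRTC target genes passed on either count, with Hdac7 at -0.41 (adjusted p = 0.0953; 0.08 in a dimmer probe set), while the list was lower as a set with a median of -0.33, or 0.00 in the scaling as deposited (camera adjusted p = 0.049; adjusted p = 0.359 with an estimated correlation). It did not pass without Lkb1 KO 5 (adjusted p = 0.122), WT 6 (adjusted p = 0.0505) or WT 7 (adjusted p = 0.143). In the unfolded protein response Sdf2l1 (0.72 ± 0.16) and Pdia4 (0.71 ± 0.16) rose and Eif2ak3 (-0.36 ± 0.08) and Dnajb9 (-0.46 ± 0.11) fell among 23, 5 and 2 when adjusted over the list alone, with a median of 0.21 (camera adjusted p = 0.0438; adjusted p = 0.376 with an estimated correlation). This call was lost without Lkb1 KO 6 (adjusted p = 0.118), KO 7 (adjusted p = 0.0637), WT 5 (adjusted p = 0.0591) or WT 6 (adjusted p = 0.101). Without 1 sample, no member of the immediate early and unfolded protein lists passed in any of the 7 fits. The count of 3 for NF-kB genes then ranged from 1 (without WT 7) to 3. With the Actb 3' to 5' ratio as a covariate the calls of the NF-kB list (adjusted p = 0.122) and the CREB list (adjusted p = 0.209) were lost. With the filter at the 60th percentile those of the CREB list (adjusted p = 0.145) and the unfolded protein list (adjusted p = 0.155) were lost. The CREB call was also lost with a pseudocount of 1 (adjusted p = 0.0516), cyclic loess (adjusted p = 0.0502) and the mean of probe sets (adjusted p = 0.112). The unfolded protein call was also lost with a floor of 32 (adjusted p = 0.0561) and the mean of probe sets (adjusted p = 0.0509). By fry the CREB, immediate early and unfolded protein lists did not pass (adjusted p = 0.0764, 0.111 and 0.0809). In the integrated stress response the pseudokinase gene Trib3 fell (-1.06 ± 0.12) and the tRNA synthetase gene Eprs rose (0.50 ± 0.09, in none of the 7 fits without 1 sample) among 24, 4 and 5 when adjusted over the list alone (median 0.07, camera adjusted p = 0.347). None of 30 interferon response genes passed, 1 higher and 1 lower when adjusted over the list alone (median 0.04, camera adjusted p = 0.544), with Oas2 at 0.96 (adjusted p = 0.0545) and Iigp1 at -0.56 (adjusted p = 0.0541).

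Cre was expressed from the Rosa26 locus in KO alone, and of 25 tested genes listed as its neighbours, Tamm41 (0.51 ± 0.10), Sec13 (0.78 ± 0.16) and Sumf1 (0.39 ± 0.09, named after its value was seen) rose and Hdac11 (-0.83 ± 0.14) and Camk1 (-0.55 ± 0.11) fell, also when adjusted over the list alone (median -0.03, camera adjusted p = 0.914). That is 20.0% of the list, against 5.39% of the other tested genes (Fisher's exact test, two-sided p = 0.00998). Without 1 sample it was 0% (without Lkb1 KO 7 or WT 6) or 4% (without any of the others), against 0.557% to 2.4% of the other genes in the same fits, with Fisher's exact p from 0.173 to 1. On GRCm38.p6, 3 tested members of the list, Hdac11 among them, were not among the 50 tested genes nearest to the locus, and of those 50 genes 4 passed, or 8.0% against 5.42% (Fisher's exact test, p = 0.348). The 4 sex-linked genes tested were too few for a list test and none passed, with Xist at -0.11 (adjusted p = 0.761) and the Y-linked gene Eif2s3y at 0.07 (adjusted p = 0.773). Across the 18 lists that passed camera's test, 9 higher and 9 lower, none passed with an estimated correlation. Of the 18, 15 passed by fry, as did 3 other lists.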

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

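Of the tests below, those of the hybridization controls, the 3' to 5' ratios, the scaling, single WT samples, p53 targets and the Rosa26 locus were chosen after the results they bear on had been seen.

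Among the 4 KO samples, the values of 7 of 121 named genes held 1 sample far from the others, where the gap to the nearest sample, as a share of the range, exceeded Dixon's critical value. Chance gives this in about 1 of 20 genes. The share of the range was 0.893 for Ly86 (KO 5 at 9.26, the others 9.01 to 9.03), 0.84 for Lcn2 (KO 4 at 8.43, the others 9.2 to 9.35), 0.919 for Pdzk1ip1 (KO 7 at 9.33, the others 9.74 to 9.78) and 0.837 for Kit (KO 5 at 10.47, the others 10.37 to 10.39). It was 0.995 for Cd48 (KO 5 at 11.25, the others 11.13), 0.883 for Nolc1 (KO 5 at 8.81, the others 9.22 to 9.27) and 0.942 for Mpo (KO 4 at 13.81, the others 13.89 to 13.9). Among 1127 probe sets with no gene or with several genes in the annotation, which no comparison above used, 56 passed limma's threshold, 23 higher and 33 lower in KO. Of 160 called genes with at least 2 probe sets past the filter, 30 had probe sets of both signs.

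The first pattern is the greater brightness of the KO arrays, a median shift of 0.343 log2 units over tested genes. Hybridization controls, which share the scanning and hybridization with the genes, were not brighter in KO (-0.0945), which argues against those steps. A difference in the length or quality of the amplified RNA stays open, since the Actb 3' to 5' ratio separated the genotypes (exact permutation p = 0.0571) and cannot be told apart from genotype in 7 arrays. A greater RNA content of KO cells was not tested, since the amount hybridized is not known here.

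The second pattern is the lower level of mature granulocyte genes in KO, with a list median of -1.51. Normalization does not account for it, as the median was -1.16 in the deposited scaling with a median standard error of 0.222, and neither does 1 WT sample, as the median nearest to 0 without 1 of them was -1.24. A smaller number of mature granulocytes carried into the KO sorts may contribute: a separate list of 16 tested neutrophil transcripts, without genes of the first lists and without Itgb2l, whose value had been seen, had a median of -0.271 and passed limma's camera before adjustment (0.0286) but not after it over 4 such tests (adjusted p = 0.0572; adjusted p = 0.591 with an estimated correlation). The lineage-negative gate is meant to remove such cells. Lower expression within LSK cells stays open and was not tested.

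The third pattern is the higher Cdkn1a in KO. A single deviating probe set stays open: the other Cdkn1a probe set exceeded the background level of 13.64 on 3 of 4 KO arrays and on no WT array, but its mean deposited signal in WT, 3.27, lies below that level, so that its log2 difference of 1.15, on which the prediction had rested, decides nothing. A p53 response, for example to Cre, could not be decided. The other p53 targets gave 0.598 in limma's camera (adjusted p = 0.783 over 4 such tests). Of these 21 targets 10 lay above 0 and 11 below, while 2, Rps27l and Zmat3, passed as higher and none as lower. Without each sample in turn, Rps27l passed in 7 of 7 fits and Zmat3 in 1. Sequence around the Rosa26 locus that came with the Cre allele stays open for calls near it, as 20 percent of the listed neighbours passed against 5.39 percent of other genes, but without 1 sample 0 or 4 percent passed against 0.557 to 2.4 percent of other genes (Fisher's exact p from 0.173 to 1), the 50 genes nearest by order gave 8 percent (Fisher's exact test, p = 0.348), and Cdkn1a is not among the listed neighbours. Loss of Lkb1 itself stays open and cannot be told apart from Cre, which no WT mouse carried.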

How the results depend on the processing

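Cyclic loess normalization, the share of Rosa26 neighbours without 1 sample and the added lists without genes named earlier were chosen after the data were seen; the other alternatives were fixed beforehand, the scaling as deposited being the one the design had taken as main. Against 200 genes higher and 239 lower, a pseudocount of 64 gave 326 and 374, the scaling as deposited 1372 and 43 (200 and 34 of them shared with the main calls), no filter 27 and 47, the filter at the 60th percentile 357 and 358, and the trend with a robust prior 460 and 455. Fewer or more genes were tested under the filters; for the others the cause was not tested. Leaving out 1 sample gave 8 to 76 higher and 35 to 119 lower, with fewer samples in the fit. Same-numbered KO and WT samples had deviations from their group means correlated at 0.0292, 0.0988 and 0.0505. These lay below 0.1, the lower bound used here for a shared pairing, so the numbers were not taken as pairs. All 3 KO samples with a partner nevertheless correlated best with the WT sample of their own number, so a pairing cannot be excluded. With the replicate block 0 genes were higher and 1 lower, with 2 residual degrees of freedom and 1697 genes at unadjusted p under 0.05, and with the Actb ratio as covariate 0 and 0. Stk11 stayed below 0 and short of the threshold in each alternative (-0.43 to -0.68 without 1 sample), and had no value at the 60th percentile filter, where it is not tested.

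With an estimated correlation 0 lists passed. Adjusted p was then 0.099 for S phase, 0.134 for mitochondrial ribosome, TCA cycle, stem cell, erythroid and B cell genes, 0.143 for NF-kB, 0.165 for megakaryocyte, 0.176 for oxidative phosphorylation, ribosome biogenesis and mast cell, 0.186 for granulocyte, 0.24 for G2 and M phase, 0.275 for myeloid progenitor, 0.348 for cell cycle inhibitors, 0.359 for CREB, 0.376 for unfolded protein and 0.44 for immediate early genes. Camera adjusted p rose past the threshold at the 60th percentile filter for B cell (0.449), CREB (0.145), mast cell (0.0937) and unfolded protein genes (0.155), and with the Actb covariate for B cell (0.0561), cell cycle inhibitors (0.515), CREB (0.209), megakaryocyte (0.1) and NF-kB genes (0.122). It did so for CREB with a pseudocount of 1 (0.0516), cyclic loess (0.0502) and the mean of probe sets (0.112), for unfolded protein genes with the floor (0.0561) and the mean of probe sets (0.0509), and for cell cycle inhibitors with the block (0.0633). Fry gave 0.0764 for CREB, 0.111 for immediate early and 0.0809 for unfolded protein genes. Leaving out 1 sample gave 0.0143 to 0.116 for cell cycle inhibitors, 0.00529 to 0.143 for CREB, 0.00408 to 0.157 for immediate early and 0.0162 to 0.118 for unfolded protein genes. Lists short of the threshold passed for ribosomal proteins as deposited (0.0154), with median centring (0.00023) and loess (0.00484), for glycolysis with the mean of probe sets (0.0168), fry (0.034) and without WT 5 (0.0457), and by fry for antioxidant (0.0423) and LKB1 genes (0.0349). The other list tests kept their side.

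In the scaling as deposited, where the median over tested genes was 0.343, signs changed for 5 list medians. These were cell cycle inhibitors (0.0368), CREB (0.00279), stem cell (0.000801), immediate early (0.03) and megakaryocyte lists (0.0914). Signs also changed there for Bcl2 (0.19), Birc2 (0.0147), Ddit4 (0.193), Flt3 (0.1), Gabarapl1 (0.00617), Kit (0.0124), Mcl1 (0.201), Ppargc1b (0.348), Procr (0.0699), Trp53inp1 (0.0789) and Xist (0.0808). They changed with the Actb covariate for Ccnd1 (-0.0969), Cdkn1c (0.201), Eif2s3y (-0.00939) and Trp53inp1 (0.195), for Mpo with median centring (-0.113) and loess (-0.0193), for Txn1 with the mean of probe sets (-0.0491) and for Ppargc1b with the block (0.00741). Without 1 sample, Bcl2 ran from -0.332 to 0.105, Ddit4 ran from -0.348 to 0.0946, Eif2s3y ran from -0.0116 to 0.135, Ppargc1b ran from -0.174 to 0.135 and Xist ran from -0.287 to 0.107. The cause was not tested. Other named genes kept their sign in each alternative. Dim genes, near the background of 13.64, have the least certain folds.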

Other observations

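The gene lists in this part were chosen after the main results had been seen, and their p-values are adjusted among these 8 lists. Lists of genes for protein breakdown, nucleotide supply, protein folding and splicing were higher in KO as sets. Of 33 proteasome genes 4 rose and none fell, 11 when adjusted over the list alone, with a median of 0.23 (camera adjusted p = 1.33e-07; adjusted p = 0.0413 with an estimated correlation), among them Psmc5 (0.60 ± 0.09 SE). Without each sample in turn, Psmc5 passed in 5 of 7 fits. Of 23 nucleotide synthesis genes 4 rose and none fell, 9 when adjusted over the list alone, with a median of 0.30 (camera adjusted p = 7.2e-07; adjusted p = 0.0466 with an estimated correlation), among them Dut (0.66 ± 0.12), Ctps (0.70 ± 0.13) and Shmt1 (0.62 ± 0.12). Dut, Ctps and Shmt1 each passed in only 1 of the 7 fits without 1 sample. In chaperonins 1 of 17 rose, Hspd1, and 8 when adjusted over the list alone, with a median of 0.28 (camera adjusted p = 3.61e-06; adjusted p = 0.0413 with an estimated correlation). Without Hspd1, whose value had been seen, none of 16 passed, 7 rose when adjusted over the list alone, and the median was 0.25 (camera adjusted p = 2.95e-05; adjusted p = 0.0413 with an estimated correlation). In spliceosome genes 3 of 27 rose, 5 when adjusted over the list alone, with a median of 0.13 (camera adjusted p = 0.0014; adjusted p = 0.0413 with an estimated correlation). The unadjusted camera p with an estimated correlation ran from 0.0112 (chaperonins) to 0.0233 (nucleotide synthesis) in these 4 lists. Among the 35 fixed lists it was lowest for S phase (0.0028) and TCA cycle genes (0.009), which did not pass after adjustment over 35 lists. Adjusted values of the added and the fixed lists therefore cannot be compared.

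In a list of 17 monocyte-lineage progenitor genes 3 rose and 1 fell, 7 and 1 when adjusted over the list alone, with a median of 0.30 (camera adjusted p = 0.000594; adjusted p = 0.0972 with an estimated correlation). The receptor gene Csf1r was at 0.75 (limma adjusted p = 0.0822). Without 3 members whose values had been seen, 1 rose and 1 fell, and the median was 0.21 (camera adjusted p = 0.025; adjusted p = 0.215 with an estimated correlation). In the full second list of 19 neutrophil genes 4 fell and none rose, 8 fell and 2 rose when adjusted over the list alone. Wfdc21 (-1.02 ± 0.17) and Ceacam1 (-0.77 ± 0.10) were among those that fell, and the median was -0.46 (camera adjusted p = 0.0028; adjusted p = 0.249 with an estimated correlation). The difference between these 2 lists was not tested. Of 9 cholesterol export and LXR target genes 1 rose and none fell, 1 rose and 4 fell when adjusted over the list alone, and the list did not pass (median -0.15, camera adjusted p = 0.246). Galectin gene Lgals1 rose (1.04 ± 0.10), and it passed without each sample in turn. All genes named in this paragraph and the one before, except Hspd1, were chosen after their values were seen.

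The large fall of Greb1, a gene induced by estrogen receptors, raised the hypothesis that estrogen-responsive genes fell together in mice whose Cre is fused to such a receptor and activated by tamoxifen. A list of such genes was written before its values were looked at, except for members already seen. The prediction left out Greb1 alone, and Ltf, whose value had been seen too, was left out as well. Of the 21 then tested, 1 rose and none fell, and 3 rose and 1 fell when adjusted over the list alone. The median was -0.08 (limma's camera, adjusted p = 0.783 over 4 such tests; adjusted p = 0.541 by fry). Without all 3 members whose values had been seen, 20 were tested and the median was -0.08 (camera adjusted p = 0.632 among the 8 added lists). The predicted fall of the list was not found. With 7 arrays a small shared fall could go unseen, so the hypothesis was not excluded. With all 23 members, Greb1 and Ltf included, the list did not pass by camera (adjusted p = 0.23) and passed downward by fry (adjusted p = 0.0228).

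The number of genes past the threshold was compared with other groupings of the same arrays. Of the 35 splits of the 7 samples into 4 and 3, 1 gave as many genes as the real one, the real split itself with 439, and the highest of the others gave 1. That is 0.0286 of the splits, under the 0.05 set beforehand and the smallest share these samples allow. It counts against chance in the grouping only if the samples are independent of each other. The labels do not state this, and a pairing by number cannot be excluded, so chance is not called excluded. The other splits mix the genotypes, and a difference between genotypes then adds to their spread, so their counts do not show how many calls unchanged samples would give.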
